A study of Potamopyrgus antipodarum with 9 samples.

How the data were processed

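Methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq) was measured in foot tissue of *Potamopyrgus antipodarum*, the New Zealand mud snail, an asexual invader of North American fresh waters. Per the labels' protocols, DNA was sheared by sonication, denatured and pulled down with an antibody against 5-methylcytidine. Each of the 9 libraries held the DNA of 10 pooled snails, with 3 pools from each of 3 lakes. Pools were taken as the replicates, so p-values measure the spread between these pools of 1 collection per lake. Lake Lytle was labelled rural, and Capitol Lake and Lake Washington urban. No library of unprecipitated input DNA was used here, so a lower count can come from less methylation or from less of the sequence.

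Per the submitters' processing notes, the tools included FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR; their versions and the genome build are not given in the sources used here. The authors deposited 1 table for Lake Lytle against Capitol Lake and 1 for Lake Washington against Capitol Lake. Both list the same 739509 windows of 100 bases on a single sequence that ends at base 73950900. The authors' read counts per window are whole numbers that were not normalised, per the file headers and the values. The deposited RPKM values are the same counts scaled by the authors to window length and library size, and were used here only to recover the number of reads per library. The deposited log2 fold changes, mean log2 CPM and p-values came from the authors' edgeR comparison, per the file headers. In the authors' deposited table a window has a p-value where its total count over the 6 libraries is at least 10, and the adjusted p-values equal a Benjamini-Hochberg adjustment. Columns of group means were not used. The 3 Capitol Lake libraries appear in both tables with 0 differing values, so the 9 libraries were put in 1 fit.

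The position of a window is its place on this concatenated sequence, and no genome or annotation was used here. Gene names, feature classes and the gene lists chosen before the data were examined are therefore not analysed here. Of the windows, 69.42% held no read in any library, and 70.55% of the 46411 empty runs between covered windows were 9 or 10 windows long. Windows with reads were grouped into 44700 covered stretches, a new one starting after at least 5 empty windows. The covered stretch stood in for the scaffold in the rule for named windows and in the clustering test. Each read was counted in 1.502 windows on average, which corresponds to a read length of 51 bases. No window exceeded a count of 300 in any library, which equals the number of distinct start positions on both strands that reach a window at that read length. The values therefore look as if each position and strand had been counted once, a step that no label or header records.

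Total window counts ran from 3039489 in Capitol Lake replicate 3 to 5013750 in Lake Lytle replicate 3. Windows with a mean count of at least 5 per library were tested, 104317 in all, 46.13% of those with a read. They held between 94.9% and 96.8% of each library's counts. Differences were tested with the quasi-likelihood F-test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with TMM scaling and robust dispersion, and called at a Benjamini-Hochberg adjusted p under 0.05. Adjusted p-values below are from this test. Contrasts were the 3 pairs of lakes and Lake Lytle against the mean of the urban lakes. A contrast of Capitol Lake against the mean of the other 2 lakes was added after the data were examined. Where all libraries of a lake had a count of 0, the fold is a lower bound against a floor of 3 counts over the 3 libraries. Floors cover counting error only, since reads copied by PCR are not independent molecules. The fit was tested on simulated data with 104317 windows. For Lake Lytle against Capitol Lake it called 48% of windows changed 2-fold and 83% of those changed 4-fold, with 5 unchanged windows called. For Lake Lytle against Lake Washington it called 49% and 82%, with 5 unchanged windows called. Simulated unchanged data for Lake Washington against Capitol Lake gave 0 calls. The simulated counts had no ceiling, and strong and weak windows did not shift against each other with depth as in the real libraries. These numbers therefore do not measure false calls in the real data.

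The rule for named windows was fixed before the data were examined. Per comparison and direction they are the 3 called windows with the largest log2 change among those with a mean count of at least 20, at most 1 per covered stretch, plus the window of smallest p, with every library of a side above every library of the other side. Separation of the lakes was tested by an exact permutation test of a pseudo-F statistic on log2 CPM with a prior count of 2. Clustering of calls was tested with 10000 permutations of the call labels. Alternatives fixed beforehand were RLE scaling, library totals, DESeq2 1.42.0, other filters and thresholds, merged windows, 6-library fits, a fit with the replicate number as a block, edgeR's exact test and leaving out each library. Alternatives added later were offsets from a loess curve of each library on mean signal, log2 depth as a covariate, thinned counts, undoing the ceiling on counts, windows under a mean count of 60, sums over covered stretches and the closest pair of libraries of each lake counted as 1. Windows with a lake mean under 1 CPM, taken as near no reads, were also examined on their own, a limit chosen after the data were examined. Figures were drawn with matplotlib 3.10.9.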

Results

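DNA methylation was profiled by MeDIP-seq in foot tissue of *Potamopyrgus antipodarum* from Lake Lytle, Capitol Lake and Lake Washington, with 3 pools of 10 snails per lake. The design asks whether populations of an asexual snail from a rural lake and from urban lakes differ in methylation. The Capitol Lake libraries held 2599314, 2536957 and 2023421 reads, the Lake Lytle libraries 2690674, 2954743 and 3339737 reads, and the Lake Washington libraries 3326100, 2764638 and 2556459 reads, as recovered from the RPKM values. Of 739509 windows of 100 bases, 104317 had enough reads to be tested, and these lay in 27213 covered stretches. Signal was concentrated: the 1% of windows with most reads took 31.3% of the counts in Lake Lytle replicate 3 and 40.7% in Capitol Lake replicate 3.

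The pools of rural Lake Lytle and urban Lake Washington lay as close to each other as pools of the same lake. Capitol Lake lay farther from both on average, but its own pools were also farther from each other. The mean distance between libraries was 0.456 ± 0.0396 log2 CPM per window (SD, 9 pairs) between Lake Lytle and Lake Washington, 0.448 ± 0.0464 (SD, 3 pairs) within Lake Lytle and 0.467 ± 0.0153 (SD, 3 pairs) within Lake Washington. Capitol Lake lay 0.611 ± 0.0938 (SD, 9 pairs) from Lake Lytle and 0.602 ± 0.0853 (SD, 9 pairs) from Lake Washington, with 0.569 ± 0.0692 (SD, 3 pairs) among its own pools. The ranges overlapped: 0.489 to 0.614 within Capitol Lake, 0.516 to 0.756 to Lake Lytle and 0.501 to 0.758 to Lake Washington. With each library's loess trend with signal removed, the means were 0.549 within Capitol Lake, 0.576 to Lake Lytle and 0.577 to Lake Washington. Depth was not in these distances, and Capitol Lake held the shallowest library. A test over all 3 lakes at once gave a separation by lake (pseudo-F 1.85, exact permutation p = 0.0107 over 280 splits). For single pairs of lakes the pseudo-F was 2.32 for Lake Lytle and Capitol Lake, 2.06 for Lake Washington and Capitol Lake, and 0.992 for Lake Lytle and Lake Washington. With the real split included, 1, 1 and 3 of 10 splits were as large, and 3 pools against 3 allow no p under 0.1. Lake Lytle and Lake Washington were thus not separated.

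**Figure D1:**
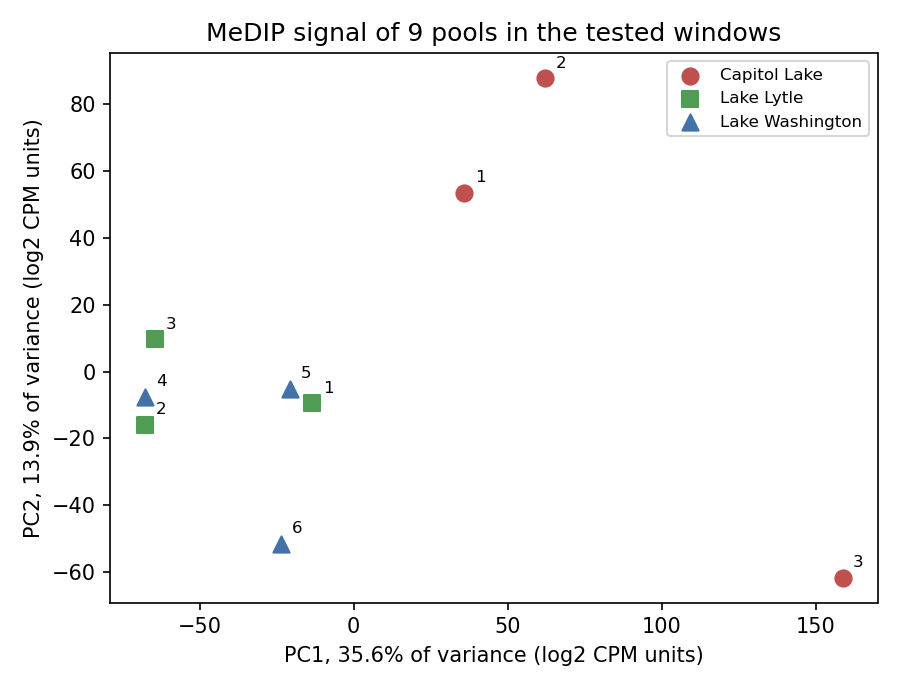
Principal components of log2 CPM over the 104317 tested windows, with PC1 (35.6% of variance) on the x axis and PC2 (13.9%) on the y axis; each point is a pool, coloured by lake and numbered by replicate. Capitol Lake replicate 3, the shallowest pool, lies farthest out on PC1 at 158.8, and the Lake Lytle and Lake Washington pools share the range from -67.6 to -13.4. The 3 deepest pools, Lake Lytle replicates 2 and 3 and Lake Washington replicate 4, lie lowest at -67.6, -64.4 and -67.6, so PC1 also moves with depth.

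Pools of a lake resembled each other closely. The biological coefficient of variation was 7.6% in Capitol Lake, 4.74% in Lake Lytle and 6.4% in Lake Washington, and correlations of log2 CPM across windows within a lake ran from 0.933 to 0.958. Windows are not independent replicates in these correlations. A chi-square over its degrees of freedom was 0.824 for Capitol Lake replicates 1 and 2, 0.794 for Lake Lytle replicates 2 and 3 and 0.878 for Lake Washington replicates 5 and 6. Over all tested windows these pairs thus differed by less than independent sampling of reads would give. In the same order the values were 0.974, 0.882 and 0.961 at a mean count of 5 to 12, and 0.393, 0.418 and 0.538 over 100. They were lowest in strong windows, where counts come nearest to the ceiling of 300. Values under 1 over all tested windows were also found for 6 of the 9 pairs of a Lake Lytle and a Lake Washington library (lowest 0.772) and for Capitol Lake replicate 1 and Lake Washington replicate 5 (0.985). At most 8.28% of tested windows had equal counts in a pair of the same lake, so no library was a copy of another from its lake. This share cannot tell separate pools from repeated sequencing of 1 pool. The 9 libraries were kept apart as labelled, without a test of their independence. The number called in each comparison is given also with each closest pair counted as 1 sample.

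Libraries also differed in how strong and weak windows stood to each other, and this moved with depth. The median log2 deviation of windows with a mean count of at least 100, minus that of windows under 25, was 0.50 in Capitol Lake replicate 3, the shallowest library, and -0.37 in Lake Lytle replicate 3, the deepest. Over the 9 libraries it fell with depth (Pearson r = -0.988, exact permutation p = 2.8e-06, adjusted 5.5e-06; Spearman rho = -1, exact permutation p = 5.5e-06, adjusted 5.5e-06). Without the 2 libraries farthest from the median depth r was -0.981. Within lakes the deeper library had the lower value in 9 of 9 pairs. Capitol Lake held the shallowest library, so the number of windows called in each comparison is given also with depth in the model.

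**Figure D2:**
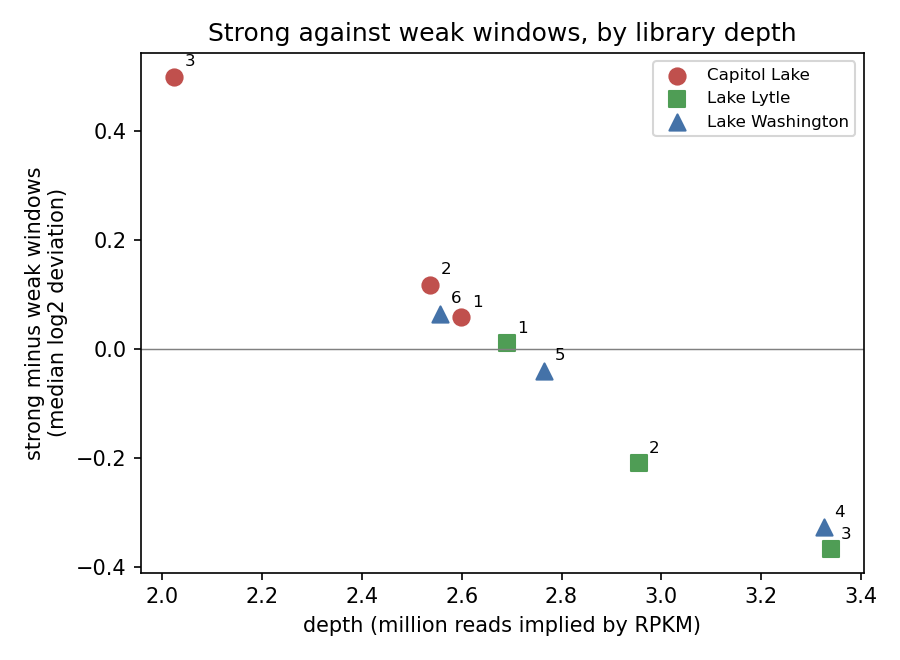
Median log2 deviation of strong windows minus that of weak windows (y axis) against depth in reads (x axis), 1 point per pool, coloured by lake and numbered by replicate. The values fall from 0.50 at 2023421 reads to -0.37 at 3339737 reads.

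Lake Lytle differed from Capitol Lake in 6298 of the tested windows (6.04%), with 3443 higher and 2855 lower in Lake Lytle. The change was at least 2-fold in 2237 of them, 1855 higher and 382 lower, and the median size was 0.81 on the log2 scale. The direction went with signal strength, as in the shift with depth above: at a mean count up to 25, 1896 were higher and 452 lower, whereas over 100, 65 were higher and 1087 lower. Over all tested windows of these classes the median log2 change was 0.19 and -0.25. The window from base 3862301 to 3862400 rose 3.88-fold, from 1.76 ± 0.607 CPM in Capitol Lake to 6.83 ± 1.37 CPM in Lake Lytle (SD, n = 3; log2 change 1.95, SE 0.31, adjusted p = 0.000592, edgeR). The windows from 26713301 to 26713400 and from 37457001 to 37457100 rose 3.64-fold and 3.45-fold, and the window from 18921801 to 18921900, with the smallest p among rises, rose 2.82-fold, from 6.35 ± 1.61 to 17.6 ± 1.77 CPM (SD, n = 3; adjusted p = 2.68e-05). The window from 47322201 to 47322300 was 3.63-fold lower in Lake Lytle, at 3.53 ± 1.58 CPM against 12.7 ± 3.1 CPM (SD, n = 3; adjusted p = 0.000287). Those from 37600101 to 37600200 and from 12178701 to 12178800 were 3.16-fold and 3.01-fold lower. The smallest p among falls belonged to the window from 2228201 to 2228300, at 8.28 ± 2.16 CPM against 24.3 ± 5.22 CPM (SD, n = 3; adjusted p = 2.44e-05).

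With log2 depth as a covariate 116 windows were called, 106 of them among the 6298; the median size of change in the 6298 went from 0.81 to 0.62 and the median SE from 0.204 to 0.237. Of the named windows, those at 26713301, 47322201, 37600101 and 12178701 were then no longer called: at 47322201 the log2 change went from -1.86 (SE 0.27) to -1.07 (SE 0.29), and at 37600101 from -1.66 (SE 0.23) to -1.38 (SE 0.30). With library totals the split was 4864 higher and 2294 lower, and with DESeq2 158 higher and 389 lower. The count was 1168 without Lake Lytle replicate 2, 1531 without Lake Lytle replicate 3, 1969 without Capitol Lake replicate 2, 2071 without Capitol Lake replicate 3, 11687 without Lake Lytle replicate 1, and 372 with closest pairs counted as 1. In the authors' deposited table the windows with an adjusted p under 0.05 number 5171, 2549 higher and 2622 lower in Lake Lytle. Among windows with a value in both, 4586 were called here and by the authors, with the same sign in 4586.

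Lake Washington, the other urban lake, differed from Capitol Lake in 3098 windows (2.97%), with 1933 higher and 1165 lower in Lake Washington. At least 2-fold changes made up 1335 of these, 1049 higher and 286 lower. The window from 73086501 to 73086600 fell 8.41-fold, from 11.8 ± 1.68 CPM in Capitol Lake to 1.43 ± 0.806 CPM in Lake Washington (SD, n = 3; adjusted p = 1.02e-07, edgeR), and those from 24770701 to 24770800 and from 37600101 to 37600200 fell 3.86-fold and 3.31-fold. The window from 8928501 to 8928600 had no read in any Capitol Lake library and 4.65 ± 0.647 CPM in Lake Washington (SD, n = 3), at least 16.1-fold higher (adjusted p = 6.41e-05). Among stronger windows, the one from 68829701 to 68829800 rose 3.98-fold, from 2.35 ± 0.472 to 9.66 ± 1.17 CPM (SD, n = 3; adjusted p = 8.72e-05), and those from 3862301 to 3862400 and from 60760201 to 60760300 rose 3.73-fold and 3.7-fold.

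With log2 depth as a covariate 186 windows were called, 171 of them among the 3098; the median size of change in the 3098 went from 0.91 to 0.77 and the median SE from 0.216 to 0.239. The window at 60760201 was then not called, its log2 change going from 1.89 (SE 0.31) to 1.65 (SE 0.36). The window at 8928501 was not called by DESeq2, where its log2 change was 6.40. DESeq2 gave no adjusted p for 58652 windows in this comparison, and a missing adjusted p counted as not called. With DESeq2 the split was 64 higher and 114 lower. The count was 480 without Lake Washington replicate 4, 727 without Capitol Lake replicate 2, 1312 without Capitol Lake replicate 3, 1640 without Lake Washington replicate 6, and 775 with closest pairs counted as 1. In the authors' deposited table the windows with an adjusted p under 0.05 number 2354, 1434 higher and 920 lower in Lake Washington, and 2192 were called both here and there, with the same sign in 2192.

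**Figure D3:**
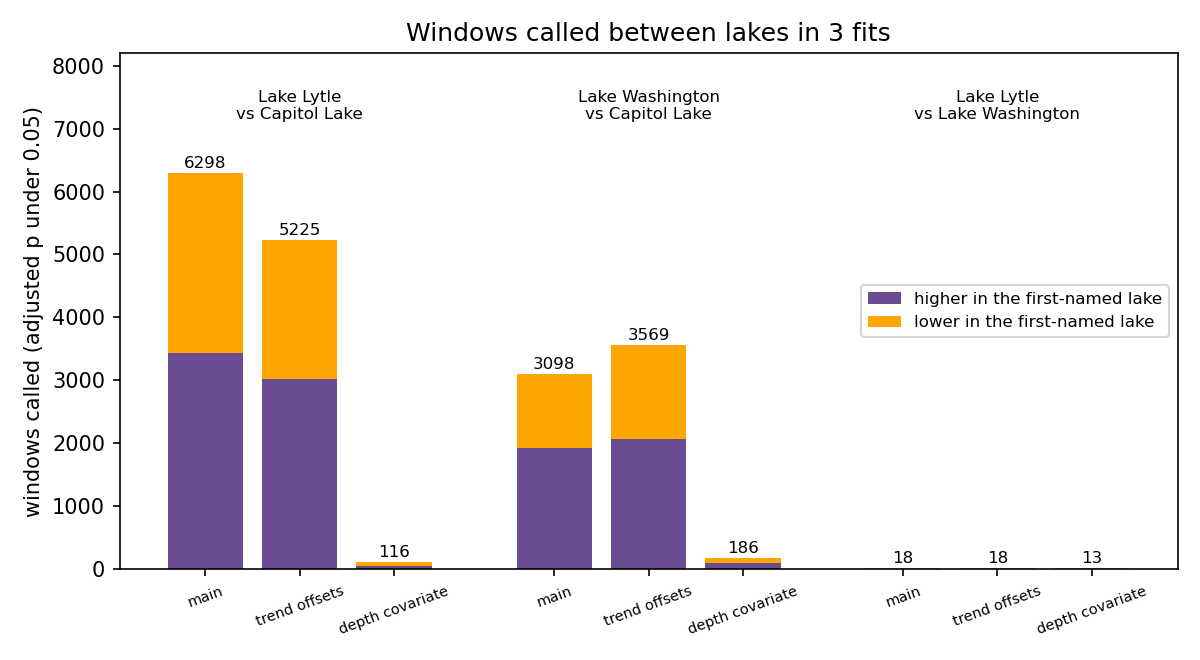
Number of windows called at an adjusted p under 0.05 (y axis) for each pair of lakes, stacked by direction, with the usual scaling ("main"), with loess offsets for each library's trend with signal ("trend offsets"), and with log2 depth as a covariate ("depth covariate"). Lake Lytle and Capitol Lake gave 6298, 5225 and 116 windows, Lake Washington and Capitol Lake 3098, 3569 and 186, and Lake Lytle and Lake Washington 18, 18 and 13.

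The windows called against Capitol Lake overlapped in part between Lake Lytle and Lake Washington. In 2201 windows both comparisons called the same direction, 1332 higher and 869 lower than Capitol Lake, and 1 window was called in opposite directions. A further 4096 windows passed the threshold in the Lake Lytle comparison only and 896 in the Lake Washington comparison only. These are not changes shown to be particular to a lake. The direct test between Lake Lytle and Lake Washington called 18 windows. Independent lists of the lengths called here would share 63.8 higher and 31.9 lower windows. With log2 depth as a covariate 66 windows were shared, 40 higher and 26 lower, where independent lists would share 0.0621 and 0.0419. In 12 simulations all 9 libraries were drawn with no change between lakes, and both comparisons then shared 0 windows on average. Unchanged data give few calls, so that count was set in advance. Across windows, which are not independent replicates, the log2 changes correlated at r = 0.808, against 0.568 in the simulations, and had a covariance of 0.199 against 0.064. The simulated counts lacked the shift of strong against weak windows with depth, so they are not a full baseline for these values. Part of the excess may come from the shared Capitol Lake libraries, which were too few to split.

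Lake Lytle and Lake Washington differed in 18 windows in 11 covered stretches, 8 higher and 10 lower in Lake Lytle. Capitol Lake lay nearer to Lake Lytle in 15 of the 18 and nearer to Lake Washington in 3. The window from 73086501 to 73086600 was 9.07-fold higher in Lake Lytle, at 12.6 ± 0.746 CPM against 1.43 ± 0.806 CPM (SD, n = 3; adjusted p = 5.73e-09, edgeR), and the one from 72325901 to 72326000 was 1.98-fold higher (adjusted p = 0.0364). The window from 52210001 to 52210100 was 4.46-fold lower in Lake Lytle, at 3.22 ± 0.538 CPM against 14.4 ± 1.1 CPM (SD, n = 3; adjusted p = 6.79e-08), and those from 40681801 to 40681900 and from 45488301 to 45488400 were 2.45-fold and 2.43-fold lower. Calls at 73086501 and 52210001 held in each alternative, but those at 72325901, 40681801 and 45488301 were lost with DESeq2, at a mean count of at least 20 and with closest pairs counted as 1. The call at 72325901 was also lost without Capitol Lake replicate 2, Lake Lytle replicate 1 or 3, or Lake Washington replicate 4 or 6. The call at 40681801 was lost without Lake Lytle replicate 2 or 3, or Lake Washington replicate 4 or 5. The call at 45488301 was lost without Lake Lytle replicate 2 or 3, or any Lake Washington replicate. With log2 depth as a covariate 13 windows were called, and those at 72325901 and 45488301 were not among them.

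A covered stretch from base 20198601 to 20199100, singled out after its values were seen, had 5 tested windows, and all 5 were called. In its window from 20198801 to 20198900 the Lake Washington libraries had no read, against 6.56 ± 0.843 CPM in Lake Lytle and 2.77 ± 0.61 CPM in Capitol Lake (SD, n = 3), at least 28.8-fold and 12.2-fold higher. At 8928501 to 8928600 the Lake Lytle libraries had no read, and Lake Washington was at least 21.5-fold higher. An unadjusted p under 0.05 (edgeR) was found for 3654 of the 104317 windows, fewer than the 5216 that no difference would give. Such a shortfall may mean that p-values were too large for this pair, so it is not evidence that the lakes are alike. DESeq2 called 8 windows. The number called between these lakes was 4 at a mean count of at least 20, 43 without a filter, 11 with closest pairs counted as 1, 11 without Lake Lytle replicate 3 and 11 without Lake Washington replicate 4.

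**Figure D4:**
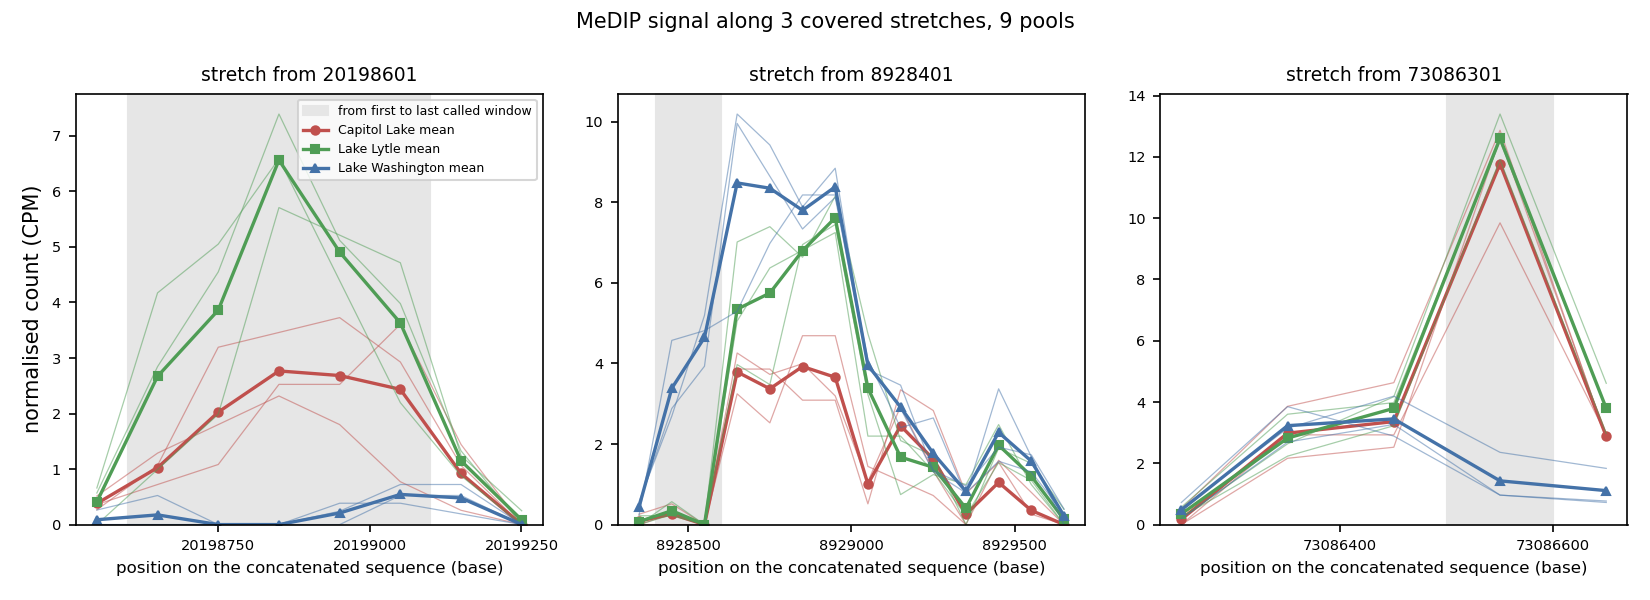
Normalised count in CPM (y axis) by position on the concatenated sequence in bases (x axis) for 3 covered stretches; thin lines are the 9 pools, thick lines with markers the lake means, and grey the span from the first to the last window called between Lake Lytle and Lake Washington. In the stretch from 20198601 the Lake Washington mean is 0 at 20198801 where the Lake Lytle mean is 6.56; in that from 8928401 the called windows lie at the left edge; in that from 73086301 Lake Washington lacks the peak of 12.6 CPM seen in Lake Lytle.

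Rural Lake Lytle differed from the mean of the urban lakes in 80 windows, 49 higher and 31 lower. Among windows with a mean count of at least 20, the largest rises were 2.23-fold at 16637501 to 16637600, where Lake Lytle had 7.81 ± 0.363 CPM, Capitol Lake 2.82 ± 0.604 CPM and Lake Washington 4.28 ± 1.01 CPM (SD, n = 3; adjusted p = 0.0132, edgeR), and 2.19-fold and 2.09-fold at 55357501 to 55357600 and 6844201 to 6844300. Among the same windows the largest falls were 2.39-fold at 40681801 to 40681900, with 3.36 ± 0.378 CPM in Lake Lytle against 8.08 ± 1.43 CPM in Capitol Lake and 8.3 ± 0.612 CPM in Lake Washington (SD, n = 3; adjusted p = 0.00378), 2.16-fold at 45488301 to 45488400 and 2.07-fold at 2228201 to 2228300. The smallest p-values belonged to the windows from 20198801 to 20198900, where the urban lakes themselves differed, and from 26188001 to 26188100, which was 1.74-fold lower in Lake Lytle.

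Lake Lytle lay outside the range of all 6 urban libraries in 41 of the 80 windows. With a single rural lake, lake and setting could not be separated. The count was 4 with log2 depth as a covariate, 3 with closest pairs counted as 1, 7 with DESeq2 and 250 with loess offsets, and the split with library totals was 86 higher and 34 lower. It was 605 without Lake Lytle replicate 1, 440 without Lake Washington replicate 4, 185 without Capitol Lake replicate 1, 20 without Lake Washington replicate 6, 19 without Lake Washington replicate 5, 14 without Capitol Lake replicate 2, 8 without Lake Lytle replicate 3 and 6 without Lake Lytle replicate 2.

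Few of these named windows held their call. With log2 depth as a covariate those at 20198801 and 26188001 were still called and the other 6 were not; at 16637501 the log2 change went from 1.16 (SE 0.20) to 1.15 (SE 0.22) and the adjusted p to 0.134 (edgeR). With DESeq2 the windows at 16637501, 55357501, 6844201, 40681801 and 45488301 were not called. Without Lake Lytle replicate 2, and with closest pairs counted as 1, the window at 20198801 alone was called. Without Lake Lytle replicate 3 the windows at 20198801, 40681801 and 2228201 were called. Calls at 55357501, 6844201 and 45488301 were lost also without Capitol Lake replicate 2, Lake Washington replicate 5 or Lake Washington replicate 6. The call at 16637501 was lost without Capitol Lake replicate 2, and the call at 55357501 without Capitol Lake replicate 1 or Lake Lytle replicate 1.

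Called windows lay next to each other along covered stretches. Between Lake Lytle and Capitol Lake 2173 neighbouring pairs were called in the same direction, 15.7 times the number expected by permutation (permutation p = 1e-04, the smallest that the draws can give). Ratios were 26.7 for Lake Washington against Capitol Lake, 5833 for Lake Lytle against Lake Washington, where 7 pairs were observed, and 556 for Lake Lytle against the urban mean, where 13 were, each with permutation p = 1e-04. These last 2 rested on few stretches: without the 10 stretches with most calls the urban-mean ratio was 0 (permutation p = 1), and 1 Lake Lytle and Lake Washington call was left. The 80 urban-mean calls lay in 67 stretches, and the 57 calls left had 1 call per stretch. No neighbouring pair was then possible, so this ratio was set in advance and tests nothing. Neighbouring windows share reads. For windows 200 bases apart, which do not, the first 2 ratios were 8.55 and 12.6. The permutation spread calls over all tested windows regardless of signal strength, which the direction of calls followed. It therefore cannot tell local changes apart from that trend. The 10 stretches with most calls held 1.76% of the Lake Lytle and Capitol Lake calls and 2.1% of the Lake Washington and Capitol Lake calls.

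Windows without a read in all pools of a lake and with at least 10 counts in each pool of another were rare, 2 in all. These were the windows at 8928501, empty in Capitol Lake and Lake Lytle, and at 20198801, empty in Lake Washington.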

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

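The contrast of Capitol Lake against the other lakes and the tests of the trend with signal strength, of a single deviating library, of the title prefixes, of depth as a covariate, of the 3 deepest libraries, of the ceiling on counts, of the windows near no reads, of the highest set of each partition, of the splits with Capitol Lake kept whole and of the lake of origin were chosen after the results they bear on were seen.

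In 18 windows the change from Capitol Lake differed between Lake Lytle and Lake Washington by a direct test of that difference. In 1 of them, at 20198801 to 20198900, both changes were called and had opposite signs: the log2 change from Capitol Lake was 1.24 (SE 0.27, adjusted p = 0.00801, edgeR) in Lake Lytle, and Lake Washington had no read.

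In 10 of the 18 windows, in 4 covered stretches, a lake had a mean under 1 CPM, at or near no reads. A trend with signal strength is argued against, since removing it by loess offsets shifted the Lake Lytle and Lake Washington log2 change of windows with a mean count under 25 by at most 0.071, whereas the smallest change among the 10 windows was 2.69. With those offsets 9 of the 10 were still called, and the other, at 20199001, went from 2.70 (SE 0.50, adjusted p = 0.034, edgeR) to 2.65 (SE 0.51, adjusted p = 0.0517). Loss or gain of a whole covered stretch cannot be told apart from a local change: 2 of the 4 stretches had a tested window at least 200 bases from a called one, where the distant change was 0.0629 and 0.271 of the called change, a median of 0.167. A change in the sequence, such as a deletion or a mismatch that stops reads from mapping, may give the same counts as a change in methylation, and with 0 input libraries these explanations cannot be told apart.

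Of the 10 splits of the 6 Lake Lytle and Lake Washington libraries 2 called as many windows, the real split with 18 and another with 21; so few splits allow no share under 0.05.

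Capitol Lake stood apart in 6298 and 3098 windows, and its libraries were also shallow. Several values argue against the trend with signal strength, a single deviating library or a difference in depth as the whole cause. With loess offsets 60.8% of the Lake Lytle and Capitol Lake calls remained with the same sign, and with thinning to equal totals as well 41.52% remained. The 3 deepest libraries against the other 6 as a single group called 8801 windows with the usual scaling and 180 with loess offsets. With those offsets the Capitol Lake split still called 7771. Without Capitol Lake replicate 3, 2071 windows were called, and Capitol Lake replicates 1 and 2 against the 3 other libraries nearest in depth called 474 windows, against at most 4 in the other 9 splits. How much of the change follows depth stays open. With log2 depth as a covariate 1.683% of the Lake Lytle and Capitol Lake calls remained with the same sign. In the windows called for Capitol Lake against the others, the change then kept a median 0.716 of its size. None of these values can tell a handling batch apart from the lake, because 0 title prefixes are shared between Capitol Lake and the other lakes. Lake Lytle and Lake Washington titles share the prefix S, whose meaning is not given. A batch shared by these lakes therefore cannot be told apart from their closeness either. A biological difference between the populations stays open too.

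Real splits of the 6 libraries called 6298 windows for Lake Lytle and Capitol Lake and 3098 for Lake Washington and Capitol Lake, 1 of 10 splits in each case, with 0 windows in the highest other split; 10 splits allow no share under 0.05. For Capitol Lake against the other lakes, 2 of 99 drawn splits called at least the 9946 windows of the real one, but this lake was chosen because it stood apart. By the highest set of each of the 33 partitions drawn, 2 of 33 called as many, a share of 0.0606, so chance is not excluded for the number called. The highest other split, with 10834 windows, set apart the 3 deepest libraries, Lake Lytle replicates 2 and 3 and Lake Washington replicate 4, which points to a structure by depth; against the other 6 as a single group these 3 called 8801 windows and the Capitol Lake libraries 11480.

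For Lake Lytle against the urban mean, 3 of the same 99 splits called at least the 80 windows of the real one, the highest other with 10834, but 1 of these was the Capitol Lake set itself, and apart from the division by lake the splits drawn broke up the Capitol Lake libraries, so this share says nothing of Lake Lytle. With Capitol Lake kept whole, 6 of 20 sets of 3 Lake Lytle and Lake Washington libraries called at least 80 windows, the highest other with 15167 for the 3 deepest; 20 sets allow no share under 0.05.

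The shift of strong against weak windows between libraries is argued not to come from the lake alone, since within lakes the deeper library had the lower shift in 9 of 9 pairs. A candidate explanation is the ceiling of 300 counts per window, which would hold back strong windows more in deep libraries. Undoing the ceiling under uniform read starts left 74.3% of the range of the shift, which neither removes nor leaves the pattern whole, so the ceiling cannot be told apart from other depth-linked effects such as a differing yield of the immunoprecipitation.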

How the results depend on the processing

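Loess offsets, undone ceiling, windows under a mean count of 60, thinning, stretch sums, closest pairs counted as 1, depth as a covariate, and the whole contrast of Capitol Lake against the other lakes were chosen after the data were examined. In order, values are for Lake Lytle against Capitol Lake (6298 windows), Lake Washington against Capitol Lake (3098), Lake Lytle against Lake Washington (18), Lake Lytle against the urban mean (80) and Capitol Lake against the others (9946); a comparison is left out where its count stayed within 1.5 times.

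At an unadjusted p under 1e-05 there were 340, 238, 32 (urban mean) and 544 (Capitol Lake) windows, and at 0.001 there were 3466, 123 (Lake Lytle and Lake Washington), 820 and 4581. DESeq2 called 547, 178, 8, 7 and 3114; it gave no adjusted p for 34382 windows in the first comparison, 58652 in the second and 84944 for Capitol Lake against the others. Merging 5 windows gave 1901, 779, 8, 4 and 3263, and summing over stretches 1605, 750, 7, 8 and 2757, with fewer units tested. Without a filter Lake Lytle and Lake Washington gave 43 and the urban mean 543; at a mean count of at least 20 the former gave 4. Windows under a mean count of 60 gave 3343 (first comparison), 41 (urban mean) and 5049 (Capitol Lake). Closest pairs counted as 1 gave 372, 775, 11, 3 and 2122, with fewer libraries. Depth as a covariate gave 116, 186, 4 (urban mean) and 294 (Capitol Lake). Thinning with loess offsets gave 3650, 143 (urban mean) and 5837 (Capitol Lake). The urban mean gave 250 with loess offsets, 211 with the ceiling undone, 520 with both and 38 with thinning; Lake Washington and Capitol Lake gave 4898 with both. Apart from fewer units or libraries, the cause was not tested.

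Leaving out each library gave 1168 to 11687, 480 to 4108, 11 to 21, 6 to 605 and 2838 to 14674 windows. For Capitol Lake against the others the split was 5014 higher and 4932 lower, 3862 and 6647 with library totals, and 2925 and 189 with DESeq2. Library totals moved the median log2 change over all windows for Lake Lytle and Capitol Lake to 0.14, from 0.05.

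With the replicate number as a block, Lake Lytle against Capitol Lake gave 3694 windows. No pairing by number was seen: correlations of deviations were -0.144, -0.0042 and -0.137, and 0 of 6 libraries correlated best with their own number. Depth fell with the number in Capitol Lake and rose with it in Lake Lytle. The shift with depth therefore works against such a correlation, so a pairing is not excluded.

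Windows without reads in a lake numbered 14 at 5 counts and 1 at 20 counts. Shared calls against Capitol Lake fell to 125 at p under 1e-05 and to 66 with depth as a covariate. Without the 10 stretches with most calls, the clustering ratio for the urban mean was 0 (permutation p = 1). This was set in advance, since each stretch left held 1 call. The ratio for Lake Lytle and Lake Washington could not be computed, since 1 call was left. Separation of the lakes kept an exact permutation p under 0.05 in each alternative run for it, none of which had depth in the model. The spread within lakes moved by less than the SD of its values over pairs of pools. That limit is wide: 0.055 for a spread of 0.076 in Capitol Lake, 0.0389 for 0.0474 in Lake Lytle and 0.0405 for 0.064 in Lake Washington. Of 831 values of named windows under alternatives, 735 kept sign and call, 96 kept the sign only and 0 reversed. Named windows were chosen for large changes or small p with no overlap between sides, so a reversal was unlikely from the start. Some windows also recur across comparisons, so these values are not separate checks. Of the 96 lost calls, 16 came with DESeq2, where a missing adjusted p counted as a loss, and 15 with depth as a covariate. Feature classes and gene lists were not run. Counting noise limits weak windows most.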

Other observations

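The contrast of Capitol Lake against the other lakes and its alternatives were chosen after the data were examined, and so were the further windows shown here. Capitol Lake against the mean of the other 2 lakes called 9946 windows, 5014 higher and 4932 lower in Capitol Lake. The count was 294 with log2 depth as a covariate, 2122 with closest pairs counted as 1 and 3114 with DESeq2, which gave 2925 higher and 189 lower. It was 2838 without Capitol Lake replicate 3, 3086 without Capitol Lake replicate 2, 4976 without Lake Lytle replicate 2, 5195 without Lake Washington replicate 4 and 5566 without Lake Lytle replicate 3. The window from 37600101 to 37600200 was 3.24-fold higher, at 12.5 ± 1.46 CPM in Capitol Lake against 4.01 ± 1.97 CPM in Lake Lytle and 3.76 ± 0.436 CPM in Lake Washington (SD, n = 3; adjusted p = 1.52e-05, edgeR). The window from 3862301 to 3862400 was 3.8-fold lower (adjusted p = 0.000172), and that from 37457001 to 37457100 was 3.55-fold lower, at 3.22 ± 0.784 CPM against 11.5 ± 2.27 CPM and 12.1 ± 1.12 CPM (SD, n = 3; adjusted p = 1.52e-05). With log2 depth as a covariate these 3 windows were still called, whereas the rises at 47322201 to 47322300 (2.97-fold) and 24770701 to 24770800 (2.65-fold) were not. DESeq2, which gave no adjusted p for 84944 windows in this contrast, called none of these 5.

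In further windows called between Lake Lytle and Lake Washington, Capitol Lake had the level of Lake Lytle. At 52062801 to 52062900 Lake Washington had 0.447 ± 0.181 CPM, against 3.04 ± 0.675 CPM in Lake Lytle and 3.31 ± 0.699 CPM in Capitol Lake (SD, n = 3; adjusted p = 0.0144 between Lake Lytle and Lake Washington, edgeR). At 43434901 to 43435000 Lake Washington had 8.18 ± 1.8 CPM, against 2.04 ± 0.177 CPM and 1.71 ± 0.371 CPM (SD, n = 3; adjusted p = 8.31e-05).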
